A study of Oryza sativa Japonica Group with 3 samples.

How the data were processed

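Poly(A)-enriched RNA from whole rice seeds of the landrace Jiucaiqing was sequenced at 0, 24 and 48 h of imbibition in distilled water, with 1 library per time point. Per the labels, RNA was extracted with a plant column kit and libraries were made from fragmented RNA by reverse transcription, adapter ligation and PCR after selection by size; each library combined 3 biological replicates, per the series design text. Pooling averages the replicates before sequencing, so their spread is not in the values and no replicate could be left out.

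The authors deposited 1 table of FPKM values per library, to 2 decimals, with 1 value per transcript isoform. Per the file headers, the tables derive from isoform-level output. FastQC, RSEM 1.1.11 and edgeR 2.3.52 are named in the submitters' processing notes without their roles. The aligner settings, the genome build, the annotation release and any scaling of FPKM between libraries are not given in the sources used here. RSEM, where it is the source of such values, divides reads that match several isoforms or similar genes by estimated probability, so values of near-identical copies and of single isoforms are less certain than those of unique loci. FPKM divides by transcript length and by the library's total, so a few very abundant transcripts lower all others.

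From the deposited FPKM, isoforms were summed per locus by the ID without its isoform suffix, giving 55986 loci, of which 49529 have 1 isoform. Loci at 1 FPKM or more in at least 1 of the 3 libraries were kept, which left 20915. Differences were taken on log2(FPKM + 1), a scale that understates the change of low loci. Since each time point is 1 library, no test was run: a locus was called higher or lower by a fixed rule of size, at least 2-fold on that scale. A locus peaked in a library where it was at least 2-fold above both others. A value of 0 in such a table can be a failed estimate. Zeros stayed in the counts, entering the scale as 0: of the loci past 2-fold, 286 were listed at 0 in 1 of both libraries for 24 h against 0 h, 219 for 48 h against 24 h and 632 for 48 h against 0 h. No locus printed with a fold is at 0 in any library. The rule for printed loci was the 2 largest differences in each direction per comparison, among loci at 10 FPKM or more in the higher of both libraries, a shortening of the planned 10 because names were lacking. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

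Before the data were examined, 35 gene lists defined by annotation wording and 33 single loci of known function had been fixed, to be used where the files or a reference table pair IDs with names. The reference table used here has 39387 genes of assembly ASM3414082v1 and was searched in 8 columns; 1 locus ID matched, LOC_Os01g19850, with the synonyms KCC2 and OsCCC2. It was at 0.46, 0.12 and 0.16 FPKM at 0, 24 and 48 h, under the filter. The lists could therefore not be matched, the single loci are not reported, and no coordinates are given, since the build behind the files is not stated.

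The relative worth of 1 read was estimated as the commonest log2 ratio of isoform values between 0.5 and 2 FPKM in a pair of libraries, within a tolerance of 0.015. The ratio was shared by 113 isoforms for 24 h over 0 h against a median of 28 at other ratios, by 106 against 34.5 for 48 h over 24 h, and by 63 against 27 for 48 h over 0 h, the weakest of these estimates. Both values were held to the same range, so ratios near 1 are commoner by construction. Part of each excess over the median can follow from that. The 3 log2 estimates closed, with 0.09 for 48 h over 0 h measured directly and 0.08 as the sum of both steps. Estimates drawn towards a ratio of 1 would close as well. On simulated whole reads, the method returned 1.08 and 0.831 for libraries with relative depths of 0.92 and 1.2. Depths further from 1 were not simulated. In a simulation of the comparison of 24 h with 0 h over 20915 loci with 200 loci changed, the size rule recovered 100% of loci changed 4-fold up or down, 96% of those changed 3-fold up and 100% of those changed 3-fold down, and 0 unchanged loci passed. The scatter used there was assumed, not measured, and held no counting noise. All changed loci had a mean of 10 FPKM or more. How often low loci pass the rule through counting noise was therefore not simulated.

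Alternatives fixed beforehand were pseudocounts of 0.1 and 5 FPKM, no filter and a filter of 5 FPKM, a rule of 4-fold, values per isoform, and 3 scalings: the same sum per library, median-of-ratios factors, and a trimmed mean of log ratios with 30% trimmed at each end. The median-of-ratios factors, over 14088 loci at 1 FPKM or more in all libraries, were 1.01, 1.02 and 0.959 at 0, 24 and 48 h, and the trimmed-mean factors were 1.03, 0.990 and 0.982. The same sum per library multiplied all values by 1.13, 1.72 and 1.87, which also lowers the weight of the pseudocount. A rescaling without LOC_Os09g00999 and one to the same sum with the mean level of the 3 libraries kept, with multipliers of 0.737, 1.12 and 1.21, were added after seeing the data, as were the classes of mean abundance, the comparison of neighbouring loci and the isoform shares.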

Results

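RNA was sequenced from seeds of Jiucaiqing, a japonica rice landrace, at 3 stages: the dry seed (0 h), the seed after 24 h in water, and the germinated seed after 48 h in water at 30 °C. Each stage was represented by 1 library, made from 3 biological replicates combined before sequencing. Abundance was given as FPKM, a fragment count scaled by transcript length and library total, for 66338 transcript isoforms of 55986 loci. With 1 library per stage there was no replicate error to set a difference against, so no p-value or SD is given and every difference below is one between 3 libraries. The deposited values carry no read totals, so the absolute depth of each library is unknown. The relative worth of 1 read was estimated by the commonest ratio between low values in a pair of libraries. It was 1.09 for 24 h over 0 h, 0.966 for 48 h over 24 h and 1.06 for 48 h over 0 h. By this estimate, which favours ratios near 1, 1 FPKM stood for a similar number of reads in all 3 libraries. The files do not pair the locus IDs with gene names, and loci are therefore given by ID, with the chromosome that the ID states.

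The number of loci at 1 FPKM or more was 16334 in the dry seed, 17216 at 24 h and 18855 at 48 h. The abundant end of the distribution went the other way. Loci at 1000 FPKM or more numbered 105 in the dry seed, 34 at 24 h and 27 at 48 h, and loci at 100 FPKM or more numbered 1001, 695 and 589. The summed FPKM was 881252 in the dry seed, 580571 at 24 h and 535327 at 48 h. In the dry seed the 100 most abundant loci held 50.1% of the summed FPKM, against 42.4% for the 100 most abundant at 24 h and 44.1% for those at 48 h. The 10 most abundant loci of each library instead held the least in the dry seed, with 21.7% against 27.3% at 24 h and 31.7% at 48 h.

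One locus on chromosome 9, LOC_Os09g00999, was the most abundant in all 3 libraries; it was singled out after its values were seen. It was at 49771 FPKM or 5.65% of the sum in the dry seed, 62040 FPKM or 10.7% at 24 h, and 109222 FPKM or 20.4% at 48 h. The next ID on that chromosome, LOC_Os09g01000, also picked after the values were seen, ranked 6th, 5th and 2nd at 0, 24 and 48 h. It was at 13374, 10626 and 16166 FPKM, or 1.52%, 1.83% and 3.02% of the sum. From 0 h to 24 h its FPKM thus fell while its share rose. Neither what these loci encode nor whether they share reads can be read from the values. With 1 library per stage, a difference in library preparation cannot be told apart from the stage of the seed. The second most abundant locus of the dry seed, LOC_Os01g15270 on chromosome 1, took 3.62% of the sum at 0 h, 4.04% at 24 h and 0.911% at 48 h, where it ranked 6th. Its FPKM fell at both steps, from 31919 at 0 h to 23480 at 24 h and 4875 at 48 h.

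Most of the 100 most abundant loci of the dry seed were not among the 100 highest at the later stages. Of the 100 loci with the highest FPKM in the dry seed, 37 were among the 100 highest at 24 h and 27 at 48 h, while 60 loci were shared between the 100 highest at 24 h and at 48 h. The 10 highest were kept more often. Of those in the dry seed, 6 were among the 10 highest at 24 h and 5 at 48 h, and 8 were shared between 24 h and 48 h. The median level of the 100 dry-seed loci was 2244 FPKM at 0 h, 279 FPKM at 24 h and 24.3 FPKM at 48 h, and 93 of the 100 were lower at 48 h than at 0 h. A set picked for its high level in 1 library lies lower elsewhere by selection alone. The 100 loci picked at 48 h, chosen in the same way, had a median of 622 FPKM at 48 h, 673 FPKM at 24 h and 437 FPKM at 0 h, and 70 of the 100 were lower at 0 h than at 48 h. These medians are of values as deposited. The same sum per library multiplies values by 1.13 at 0 h, 1.72 at 24 h and 1.87 at 48 h. It would raise the later medians against those at 0 h, so how level the 48 h set appears depends on scaling. By share of the summed FPKM both sets were smaller outside the library they were picked in: the dry-seed set held 50.1% at 0 h and 34.8% at 48 h, and the 48 h set held 44.1% at 48 h and 25.96% at 0 h. LOC_Os09g00999 is in both sets and alone held 5.65% at 0 h and 20.4% at 48 h. It thus softens the fall of the dry-seed set and makes up much of the difference in the 48 h set.

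**Figure D1:**
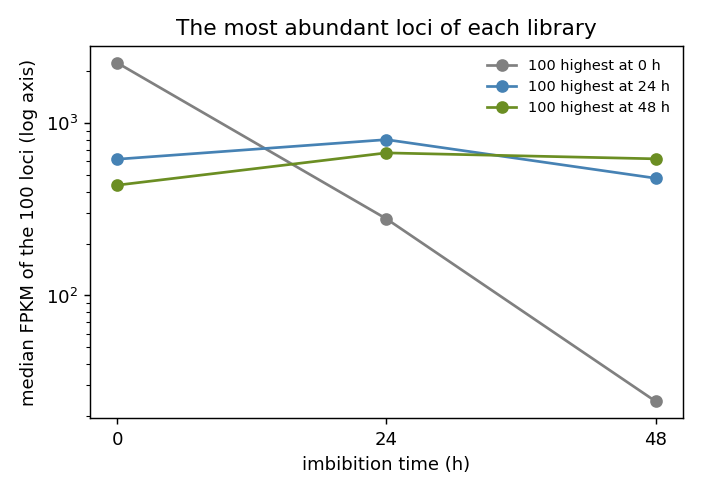
Median FPKM (log axis) of the 100 most abundant loci of each library, against imbibition time in hours; each line follows 1 set of 100 loci through the 3 libraries, with no replicates. In the values as deposited, the set picked in the dry seed goes from 2244 to 24.3 FPKM. The set picked at 48 h lies between 437 and 673 FPKM in all 3 libraries as deposited, a course that depends on scaling.

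The comparison of 24 h with 0 h addressed the seed's first day in water. Over the 20915 loci at 1 FPKM or more in at least 1 library, 3701 were at least 2-fold higher at 24 h and 3213 at least 2-fold lower, on the log2(FPKM + 1) scale, which together made up 33.1% of the loci. At least 8-fold differences were found for 424 loci higher and 384 loci lower. The 384 loci held 30.8% of the summed FPKM of the dry seed and 2.86% of that at 24 h, whereas the 424 loci held 0.191% at 0 h and 6.80% at 24 h. On this scale, the largest positive differences were those of LOC_Os10g40440 and LOC_Os10g40480, both on chromosome 10. With a pseudocount of 0.1 FPKM they ranked 4th and 1st, with log2 differences of 9.17 and 9.66. LOC_Os10g40440 was at 2.51 FPKM in the dry seed and 1498 FPKM at 24 h, a log2 difference of 8.74, and LOC_Os10g40480 was at 0.36 FPKM and 373 FPKM, a log2 difference of 8.10. The largest negative differences were those of LOC_Os11g26760 on chromosome 11, from 2745 FPKM to 44.1 FPKM with a log2 difference of -5.93, and of LOC_Os01g45659 on chromosome 1, from 643 FPKM to 10.6 FPKM with a log2 difference of -5.79. These 2 loci ranked 6th and 7th with a pseudocount of 0.1 FPKM. They ranked 3rd and 5th when rescaled to the same sum, and 1st and 3rd when that kept the mean level of the libraries. When each library was instead rescaled to the same sum, 6663 loci were higher and 1968 lower, and the higher share of the loci past 2-fold went from 53.5% to 77.2%. With a pseudocount of 5 FPKM, 1696 were higher and 1759 lower.

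The comparison of 48 h with 24 h addressed the step from the imbibed to the germinated seed. It gave fewer loci past 2-fold, with 2883 higher and 2274 lower at 48 h, or 24.7% of those measured. At least 8-fold differences were found for 178 loci higher and 139 loci lower. LOC_Os05g12640 on chromosome 5, a locus with 5 listed isoforms, was at 0.24 FPKM at 24 h and 162 FPKM at 48 h, a log2 difference of 7.04. LOC_Os12g36240 on chromosome 12 was at 16.2 FPKM in the dry seed, 2.17 FPKM at 24 h and 226 FPKM at 48 h, a log2 difference of 6.16 for this step. With a pseudocount of 0.1 FPKM these loci ranked 1st and 28th among positive differences, and with 5 FPKM 3rd and 2nd. They ranked 1st and 5th when rescaled to the same sum. LOC_Os01g06630 on chromosome 1 was lower, at 536 FPKM against 7.40 FPKM, a log2 difference of -6.00. LOC_Os05g49440 on chromosome 5 was also lower, at 394 FPKM against 8.36 FPKM, a log2 difference of -5.40. The direction of the majority depended on low loci: with the filter raised to 5 FPKM, 1697 loci were higher and 2081 lower, and with a pseudocount of 5 FPKM 945 were higher and 1149 lower. Rescaling kept the majority higher. The same sum gave 3983 higher and 2232 lower, the sum without LOC_Os09g00999 gave 4862 and 1830, and median-of-ratios factors gave 3213 and 1952.

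The comparison of 48 h with 0 h spanned the whole course and gave the most differences, with 5760 loci at least 2-fold higher and 4265 at least 2-fold lower, 47.9% of the loci measured. At least 8-fold differences were found for 826 loci higher and 739 lower. The 739 lower loci held 44.0% of the summed FPKM in the dry seed and 1.66% at 48 h; the 826 higher loci held 0.180% in the dry seed and 9.52% at 48 h. LOC_Os10g40440 was at 2857 FPKM at 48 h with a log2 difference of 9.67, and LOC_Os10g21670 on chromosome 10 was at 0.61 FPKM in the dry seed, 76.0 FPKM at 24 h and 798 FPKM at 48 h with a log2 difference of 8.96. With a pseudocount of 0.1 FPKM these were 10.10 and 10.13, ranked 4th and 2nd. LOC_Os01g06630 was at 6988 FPKM in the dry seed and 7.40 FPKM at 48 h, a log2 difference of -9.70. LOC_Os11g26570 on chromosome 11 was at 2947 FPKM, 52.4 FPKM and 3.07 FPKM at 0, 24 and 48 h, a log2 difference of -9.50. The median log2 difference of all loci was 0.18 for the values as deposited and 0.79 with the libraries rescaled to the same sum, under which 9213 loci were higher and 2740 lower, a higher share of 77.1% against 57.5% as deposited. With a pseudocount of 5 FPKM, 2509 loci were higher and 2638 lower.

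**Figure D2:**
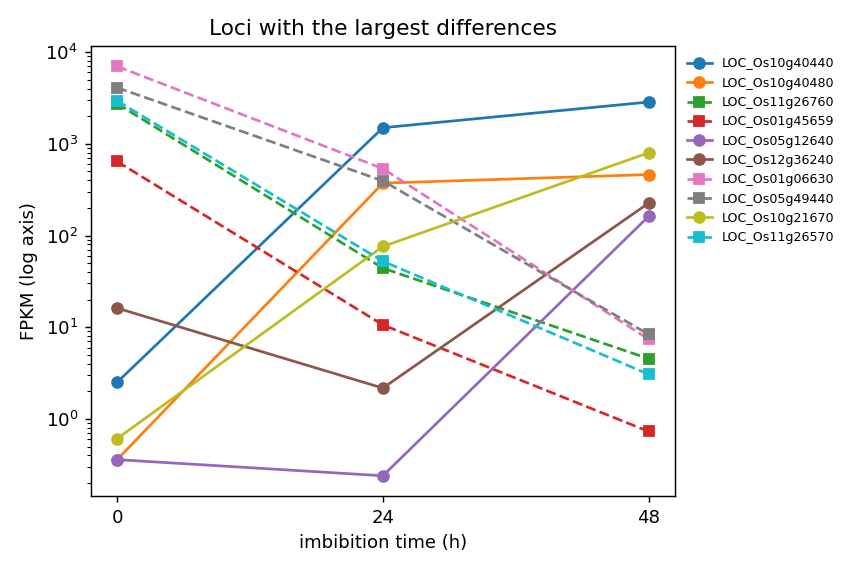
FPKM (log axis) against imbibition time in hours for the loci with the largest differences of each comparison on log2(FPKM + 1); each line is 1 locus over the 3 libraries, solid for loci higher and dashed for loci lower at the later time of the comparison that named them. LOC_Os10g40440 goes from 2.51 to 2857 FPKM and LOC_Os01g06630 from 6988 to 7.40 FPKM.

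The direction of the difference between 48 h and 0 h varied with the class of mean abundance. The mean includes the libraries compared, so loci high at 1 stage alone enter a high class through that stage. Loci at 100 FPKM or more numbered 1001 in the dry seed and 589 at 48 h. Part of the order below can therefore follow from how the classes were formed. Among loci with a mean of 1 to 5 FPKM over the 3 libraries, 2409 were higher and 1001 lower, so that 70.6% of those past 2-fold were higher. The share was 54.6% at a mean of 5 to 20 FPKM, 37.9% at 20 to 100 FPKM and 30.2% at 100 FPKM or more, where 164 loci were higher and 379 lower. From 24 h to 48 h the same share went from 81.0% at 1 to 5 FPKM to 15.9% at 100 FPKM or more, and from 0 h to 24 h it went from 58.8% to 34.8%. The lowest class, with a mean under 1 FPKM, did not extend the order in every comparison: its higher share was 72.3% for 48 h against 0 h and 91.4% for 48 h against 24 h, but 30.1% for 24 h against 0 h, with 102 loci higher and 237 lower. In the class of 100 FPKM or more, rescaling to the same sum gave a higher share of 47.9% for 48 h against 0 h, and rescaling without LOC_Os09g00999 gave 53.5%. The majority of loci past 2-fold in this class thus turned only under the latter rescaling, chosen after seeing the data.

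**Figure D3:**
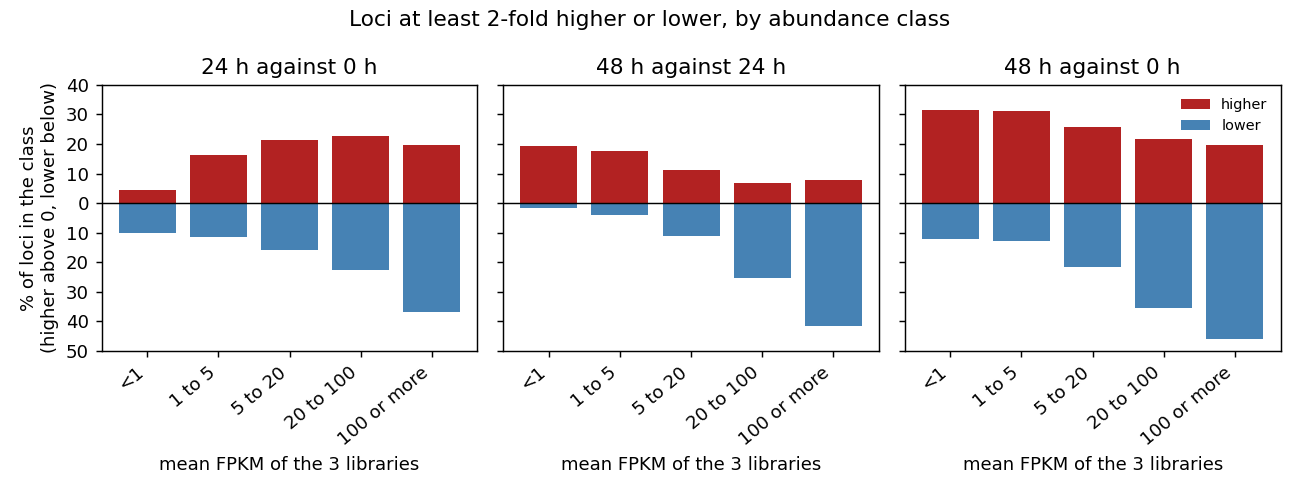
Percent of the loci in each class of mean FPKM over the 3 libraries that were at least 2-fold higher (above 0) or lower (below 0), with 1 panel per comparison and values as deposited, without replicates. At 48 h against 0 h, 31.2% of loci at 1 to 5 FPKM were higher and 12.9% lower, while at 100 FPKM or more 19.8% were higher and 45.8% lower.

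Over the 3 libraries together, 2574 loci were highest in the dry seed by at least 2-fold over both other stages, 543 were highest at 24 h and 2293 were highest at 48 h. The opposite profile, lowest by at least 2-fold, was found for 2804 loci in the dry seed, 260 at 24 h and 1436 at 48 h. These counts depended on scaling and pseudocount. Rescaled to the same sum, 1513 loci were highest in the dry seed and 3479 at 48 h, and 5344 were lowest in the dry seed; without LOC_Os09g00999 in the sum these were 1372, 4319 and 6110. The stage with the most such loci turned from the dry seed to 48 h under these scalings and, by a small margin, under median-of-ratios factors, with 2519 and 2548 loci, and a pseudocount of 0.1 FPKM, with 3254 and 3281. At both steps, 510 loci were at least 2-fold higher than at the step before and 700 at least 2-fold lower, while 10869 passed 2-fold at neither step. Across loci, which are not independent replicates, the levels at 24 h and 48 h had a Spearman correlation of 0.82, those at 0 h and 24 h one of 0.77, and those at 0 h and 48 h one of 0.57.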

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

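No replicate could be left out. No paired analysis was possible because each time point is 1 pooled library. The planned gene-list medians gave no value, since IDs could not be paired with names, and leaving out the filter moves no count by construction. Of 114 other alternative values of the counts of loci higher, lower, peaking or dipping, 61 stayed within 1.5 times the value reported, including all those under median-of-ratios factors and the trimmed mean of log ratios. Counts are given here in the order higher, then lower. At 4-fold, they were 1205 and 947 for 24 h against 0 h, 668 and 415 for 48 h against 24 h, and 2164 and 1609 for 48 h against 0 h, with 791, 51 and 564 loci peaking and 873, 18 and 315 dipping at 0, 24 and 48 h. A pseudocount of 5 FPKM gave 1696 and 1759, 945 and 1149, and 2509 and 2638, so lower loci were then the majority in each comparison, with 1542, 272 and 762 loci peaking and 1134, 71 and 755 dipping. A pseudocount of 0.1 FPKM gave 5553 higher loci for 24 h against 0 h, and 4578, 810 and 2168 loci dipping. A filter of 5 FPKM gave 1697 higher loci for 48 h against 24 h, 3641 for 48 h against 0 h and 1335 peaking at 48 h, because fewer loci were kept. Rescaling to the same sum gave 6663 and 1968 for 24 h against 0 h, and 9213 and 2740 for 48 h against 0 h, with 1513 loci peaking at 0 h and 3479 at 48 h and 5344 dipping at 0 h. Doing so without LOC_Os09g00999, an alternative chosen after seeing the data, gave 7195 and 1872 for 24 h against 0 h, 4862 higher loci for 48 h against 24 h, 10539 and 2330 for 48 h against 0 h, 1372 and 4319 loci peaking at 0 and 48 h, and 6110 and 954 dipping there. Both also raise all values against the fixed pseudocount. With the mean level of the 3 libraries kept instead, another alternative chosen after seeing the data, the same sum gave 5922 and 1701 for 24 h against 0 h, 3490 and 1977 for 48 h against 24 h, and 8564 and 2461 for 48 h against 0 h, with 1348 loci peaking at 0 h, and 4637 and 168 dipping at 0 and 24 h. In the order of these 3 rescalings, medians of all loci were 0.50, 0.57 and 0.44 for 24 h against 0 h and 0.79, 1.01 and 0.72 for 48 h against 0 h. The loci printed for the largest differences kept their direction and stayed past 2-fold in all 84 alternative values, with absolute log2 differences from 4.90 to 10.7. They were picked as the extremes, so they could hardly have fallen under 2-fold, and this says nothing of other loci. Loci printed for their abundance or their isoforms were not included. Which loci rank highest depended on the setting: of the 12 places, 7 were kept with a pseudocount of 0.1 FPKM, 7 with 5 FPKM, 9, 9 and 10 under these rescalings and 12 under the other 2 scalings. Without read totals, the counting error of a single low value cannot be given.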

Other observations

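Isoforms and the order of loci were looked at after the data had been seen, and all tests in this part except those of low and noisy loci and of variation between libraries were chosen after the result was seen. Among 1622 loci with at least 2 isoforms and 10 FPKM or more in every library, the most abundant isoform differed between 48 h and 0 h in 236 loci, or 14.5%, between 24 h and 0 h in 195 and between 48 h and 24 h in 145. In 77 loci the exchange between 0 h and 48 h moved both isoforms by at least 50 points of the locus's FPKM. At 100 FPKM or more in every library this held for 5 of 120 loci, named here after their values were seen: LOC_Os01g08560, LOC_Os01g34480, LOC_Os02g06640, LOC_Os04g33110 and LOC_Os10g30580. The isoform LOC_Os01g08560.2 held 88.0% of its locus in the dry seed and LOC_Os02g06640.4 held 71.3%, and both were listed at 0 at 48 h. A listed 0 can be a failed estimate: in 53 of the 236 loci, 39 of the 77 and 2 of the 5, at least 1 of both isoforms was listed at 0 in the library where it was not the main one. Isoform values rest on how shared reads were divided, which the deposited values do not show.

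The order of loci along the 12 chromosomes was read from the IDs. Next measured loci had log2 differences that went together, with a Pearson r across loci of 0.12 for 24 h against 0 h, 0.08 for 48 h against 24 h and 0.12 for 48 h against 0 h. The highest r in 1000 shuffles of the order within chromosomes was 0.02 in each comparison. For 48 h against 0 h, 11 unbroken runs of 8 or more loci were past 2-fold, and all 11 were higher at 48 h. Higher loci outnumber lower ones there, and no shuffle of 200 gave more than 3 higher runs of that length or more than 1 lower run, though the longest shuffled run, of 11 loci, was as long as the longest observed. For 24 h against 0 h there were 2 such runs against at most 1 in a shuffle, and the longest had 11 loci against 8; for 48 h against 24 h there was 1 against at most 1, with 9 loci against 8. One run of 10 loci on chromosome 10 holds LOC_Os10g40440 and LOC_Os10g40480, and one of 11 loci on chromosome 12 holds LOC_Os12g36240. Chromosome 11 had 15.8% of its loci lower at 48 h than at 0 h, under the lowest value of 16.4% for any chromosome in 1000 shuffles of loci between chromosomes; its 30.7% of loci higher lay within the shuffled range, as did its share of lower loci in the other comparisons, at 12.4% for 24 h against 0 h and 8.68% for 48 h against 24 h, and shuffles ignore that neighbours go together.

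A trend along or between whole chromosomes does not account for the likeness of neighbours at 48 h against 0 h, since the Pearson r of loci 50 apart was 0.00095 against 0.12 for next loci. The likeness was not confined to low loci, since r was 0.10 for next loci at a mean of 5 FPKM or more. Noise that is independent between loci could only weaken r, so this value is no test of such noise. Reads divided between similar copies that lie side by side may still account for part of it. For loci 5 apart r was 0.019, under the highest shuffled r of 0.022 for next loci. For loci 10 apart r was 0.016, still positive. Either shared reads or shared control of neighbours could give likeness that weakens over so few loci. Transcript sequences, which would separate these, were not used here. That adjacent loci are switched on together during imbibition is a hypothesis and remains open beside shared reads.

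The opposite directions of abundant and rarer loci at 48 h against 0 h were weighed in the same way. The classes rest on the mean of the same libraries, and other ways of forming them were not tried. The higher share of loci past 2-fold at a mean of 1 to 5 FPKM exceeded that at 100 FPKM or more by at least 35.3 points in 6 settings. These were the deposited values and rescalings of them, some nearly alike. A factor per library moves all loci by about the same log2 amount. It could hardly have closed the gap, so no conclusion on scaling is drawn from this. Scaling does shift the higher share among loci past 2-fold at 100 FPKM or more, from 30.2% as deposited to 47.9% with the same sum. It was 53.5% when the sum left out LOC_Os09g00999, a rescaling chosen after seeing the data. More reads per FPKM at 48 h would show more rare loci. The estimated worth of 1 read at 48 h was 1.06 times that at 0 h, from the weakest mode of the 3 estimates. Both steps added to nearly the same value. The estimate favours ratios near 1 by construction, so it does not settle this explanation. Variation between pooled libraries cannot be told apart from the stage of the seed, because there was 1 library per time point.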
